A study of Homo sapiens with 12 samples.

How the data were processed

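RNA was measured by sequencing in 12 libraries of 2 human colorectal cancer cell lines, HCT116 and RKO, in 4 groups of 3 libraries. HCT116 carried an empty vector or an overexpression construct of CKAP2L. RKO carried a negative control or a short hairpin RNA against CKAP2L. Per the labels' protocols, RNA was extracted with Trizol, treated with DNase I and made into libraries with an mRNA sequencing kit; whether the kit marks strand is not given in the sources used here. Groups and replicate numbers were taken from the library titles. The genotype labels of RKO shCKAP2L replicates 2 and 3 name other symbols than their titles do, and the titles were used. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

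The authors deposited 1 table per line with TPM (the share of each gene among a library's transcripts, adjusted for length and scaled to a fixed total) for 20263 Ensembl genes, 1 column per library. Per the submitters' processing notes, FastQC 0.11.2, Trimmomatic 0.36, HISAT2 2.0 and bedtools 2.26.0 were used with genome build GRCh38. The counting tool, the gene annotation and the treatment of strand and of reads with several matches are not given in the sources used here. The deposited TPM values have 2 decimals and each column sums to the same total within rounding. TPM keeps no depth, so the sequencing depth of each library is unknown and no counting interval was computed. TPM is a share: a change in abundant transcripts moves every other gene's value. No pair of columns was identical, and 8 genes that every cell uses were above 0 in every library.

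Gene symbols came from a gene name table for 20148 identifiers and from GENCODE release 29 (GRCh38) for 76 others, and 39 had none. By GENCODE, 19722 were protein-coding. Genome positions of named genes are those of GENCODE release 29, which may differ from the annotation the authors used.

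Values were analysed as log2(TPM + 1), separately in each line, for genes with a mean TPM of at least 1 over the 6 libraries. This kept 12732 genes in HCT116 and 11442 in RKO. Groups were compared with limma 3.58.1 in R 4.3.3 (trended prior variance, no covariates), and p-values were adjusted by the Benjamini-Hochberg method. A gene was called changed at an adjusted p under 0.05. All fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low TPM, and each ± after one is its standard error (SE). Unless another method is named, each adjusted p is from limma. The test is two-sided.

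Gene groups were 24 lists, of which 21 had at least 5 tested members in each line. These were tested with limma's camera, which compares a list's test statistics with those of all other genes. It used a preset correlation between genes of 0.01 and adjustment over the lists. The correlation was also estimated from the data as an alternative. The lists cover EGFR ligands and receptors, the STAT3 pathway, ERK output, growth factor immediate early genes, G2/M and spindle, G1/S and DNA replication, p53 targets, interferon response, NF-kB and cytokines, epithelial-mesenchymal transition, colon epithelial identity, WNT targets, hypoxia and glycolysis, cholesterol synthesis, ATF4 and the unfolded protein response, MYC targets and ribosome biogenesis, AHR and NRF2 targets, apoptosis regulators, histones, mitochondrially encoded mRNAs, ribosomal proteins, and markers of fibroblasts, immune cells and endothelium. Some genes stand in several lists.

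Agreement between the lines was measured among genes tested in both as the number called in both with opposite or equal signs, with Fisher's exact test (two-sided) per direction. The difference between the lines was tested in a joint limma model of the 12 libraries, as (HCT116 CKAP2L minus vector) minus (RKO NC minus shCKAP2L). The lines come from separate tables and differ in the manipulation too, so line and manipulation cannot be separated in that contrast.

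Named genes followed a rule. CKAP2L, STAT3, AREG and EGFR, from the study's title, were always named. Per line and direction, the 10 changed genes with the largest fold change were named, among those with a mean TPM of at least 5, no overlap of the groups' values and a gene symbol. Per list, up to 4 members with the smallest adjusted p were named. For genes changed in both lines with opposite signs, the 10 per direction with the largest smaller fold change were named, and for the difference between lines the first 5 listed genes per direction. A few genes that these rules name are not reported here. Other genes named in the text are said to be chosen after their values were seen. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined.

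The limma and camera steps were tested on simulated data with the real means and spreads and 200 genes changed by a known amount. In HCT116, 63.2%, 90.9% and 98.5% of genes changed by 0.25, 0.5 and 1 on the log2 scale were recovered, and in RKO 69.1%, 97% and 100%. Of the calls, 5.5% were false in HCT116 and 3.3% in RKO. The joint model recovered 91% of 100 genes that differed by 0.5, with 9 false calls. Camera called a planted list in both lines, and 0 other lists in HCT116 and 1 in RKO. Simulated genes varied independently and far fewer were changed than passed in the real data, so these rates may not carry over.

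Alternatives were pseudocounts of 0.1 and 5, no filter and a mean TPM of at least 5, median-of-ratios rescaling, quantile normalization, a constant prior variance, a robust prior, the replicate number as a block, and leaving out each library in turn. After the data were seen, 2 were added: TPM rescaled without the 13 mitochondrial mRNAs, and removal of each library's trend on GC content and transcript length, with splines of 4 degrees of freedom. That removal kept each library's mean over genes. A search of 3' UTRs for 7-base words, in Python 3.11.15 with NumPy 2.4.6, was also added then. No count test was run, since the tables hold no counts. Reads, protein levels, phosphorylation and the hairpin sequences were not analysed here.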

Results

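The data were mRNA profiles of HCT116 and RKO, 2 established human colorectal cancer lines. In HCT116, 3 libraries with a CKAP2L overexpression construct were compared with 3 libraries with empty vector. In RKO, 3 libraries with a short hairpin against CKAP2L (shCKAP2L) were compared with 3 libraries with a negative control (NC). CKAP2L encodes a protein of the mitotic spindle. The study's title places CKAP2L, STAT3, AREG and EGFR in 1 axis, so the question put to both comparisons was how the mRNAs of this axis and other genes moved with the CKAP2L level. Sequencing depth is unknown, since TPM keeps none. Between 16450 and 16684 genes were above 0 per HCT116 library, and between 14181 and 14573 per RKO library. Pearson's r of log2 values across genes (which are not independent replicates) was 0.9971 to 0.9978 within and 0.9951 to 0.9957 between HCT116 groups. In RKO it was 0.9988 to 0.9991 within and 0.9862 to 0.9866 between groups.

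CKAP2L itself (ENSG00000169607, GRCh38 chromosome 2, 112736607 to 112764677, minus strand) moved as the labels state in every library. In HCT116 it was at 14.02 ± 1.21 TPM (SD, n = 3) with vector and 226.8 ± 6.8 (SD, n = 3) with the construct, a TPM ratio of 16.2 (log2 fold change 3.93 ± 0.053, adjusted p = 1.41e-15). In RKO it fell from 24.88 ± 0.88 TPM (SD, n = 3) to 7.99 ± 0.507 (SD, n = 3), which was 67.9% lower (log2 fold change -1.53 ± 0.048, adjusted p = 1.21e-12). TPM does not tell the construct's transcript from the cell's own.

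AREG, which encodes amphiregulin, a ligand of the EGF receptor (ENSG00000109321, chromosome 4, 74445134 to 74455009, plus strand), was higher with CKAP2L in HCT116 and lower with its knockdown in RKO. In HCT116 it rose from 240.3 ± 7.03 to 309.1 ± 4.69 TPM (SD, n = 3 each; log2 fold change 0.36 ± 0.031, adjusted p = 2.95e-06). In RKO, where its level was low, it fell from 2.617 ± 0.437 to 1.39 ± 0.546 TPM (SD, n = 3 each; log2 fold change -0.61 ± 0.129, adjusted p = 0.000599). At this level the size depended on the pseudocount, from -0.91 at 0.1 to -0.26 at 5. STAT3, the transcription factor (ENSG00000168610, chromosome 17, 42313324 to 42388568, minus strand), was at 91.62 ± 3.48 TPM with vector and 96.74 ± 1.6 with CKAP2L in HCT116 (SD, n = 3 each), a difference that did not pass (log2 fold change 0.08 ± 0.037, adjusted p = 0.153). Without HCT116 vector replicate 3 the STAT3 difference passed, at 0.11 (adjusted p = 0.0272), and over all 17 alternatives the adjusted p ran from 0.0272 to 0.701. In RKO STAT3 rose with the knockdown, from 31.82 ± 1.93 to 42.4 ± 1.46 TPM (SD, n = 3 each; log2 fold change 0.40 ± 0.042, adjusted p = 5.49e-07). EGFR, the receptor (ENSG00000146648, chromosome 7, 55019021 to 55211628, plus strand), was at 27.37 ± 1.12 and 27.65 ± 1.22 TPM in HCT116 (SD, n = 3 each; adjusted p = 0.876), with a sign that turned under other scalings. In RKO EGFR fell from 12.85 ± 0.393 to 10.58 ± 0.501 TPM (SD, n = 3 each; log2 fold change -0.26 ± 0.047, adjusted p = 0.000159).

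**Figure D1:**
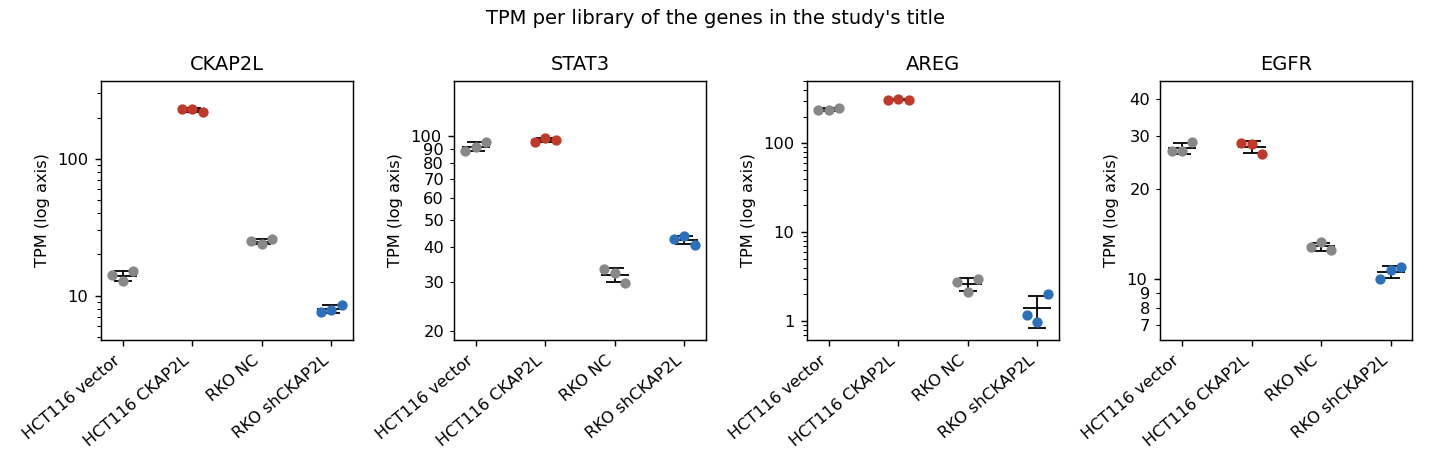
TPM per library (log axis) of CKAP2L, STAT3, AREG and EGFR in the 4 groups, with dots for libraries and bars for the mean and SD of 3. AREG is higher with CKAP2L in HCT116 (309.1 against 240.3 TPM) and lower with shCKAP2L in RKO (1.39 against 2.617), while STAT3 is higher with shCKAP2L (42.4 against 31.82).

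In HCT116, genes of the interferon response, cholesterol synthesis and the ATF4 and unfolded protein response rose with CKAP2L, and most mitochondrially encoded mRNAs fell. After CKAP2L, the genes with the largest rise were KRT17, a basal keratin (5.49 to 18.4 TPM, log2 fold change 1.58 ± 0.07), and the interferon-induced antiviral genes IFIT3 (3.98 to 10.7 TPM, 1.24 ± 0.1), IFIT2 (5.29 to 13.3 TPM, 1.19 ± 0.09), BST2 (5.59 to 13.9 TPM, 1.18 ± 0.08) and IFIT1 (5.97 to 13.5 TPM, 1.06 ± 0.09). IL20RB, a cytokine receptor subunit, rose by 0.87 ± 0.09, the neutrophil chemokine CXCL1 by 0.80 ± 0.07, the metallothionein MT1E by 0.76 ± 0.05 and the interferon-induced IFI27 by 0.75 ± 0.08. The largest decreases were smaller. CYP24A1, the enzyme that inactivates vitamin D, went from 27.6 to 19 TPM (-0.51 ± 0.05). BMP6, a secreted growth factor, changed by -0.48 ± 0.08, LRRC73 by -0.47 ± 0.08, the metalloprotease ADAM19 by -0.43 ± 0.06 and IGFBP3, a binding protein of insulin-like growth factors, by -0.42 ± 0.07. CCDC61 (-0.41 ± 0.08) and LRRC45 (-0.39 ± 0.05), which encode centrosomal proteins, ATP5MC1 (-0.40 ± 0.05), a subunit of mitochondrial ATP synthase, the olfactory receptor gene OR51I1 (-0.40 ± 0.08) and CPA4 (-0.40 ± 0.03), a carboxypeptidase, fell too. Each of these genes had n = 3 per group and an adjusted p of 0.003 or less.

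Altogether 2625 of 12732 genes passed in HCT116, 2082 higher and 543 lower with CKAP2L (16.4% and 4.3% of tested genes). Changes were small, with a median absolute log2 fold change of 0.21 among these genes, and 6 genes rose and 0 fell by 2-fold or more (limma; 4390 genes had an unadjusted p under 0.05). The excess of higher genes depended on scaling. Median-of-ratios rescaling gave 1128 higher and 1188 lower, quantile normalization 1102 and 1131, and TPM without mitochondrial mRNAs 1158 and 959. Groups did not overlap for 37.3% of genes, where chance gives 10%.

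Of 25 interferon response genes tested in HCT116, 23 rose and 0 fell (24 and 0 adjusted over the list alone), with a median log2 fold change of 0.46 (camera, adjusted p = 3.43e-17, and adjusted p = 0.0484 with an estimated correlation). ISG15, a ubiquitin-like protein, rose from 343.3 to 518 TPM. Of 25 cholesterol synthesis genes, 19 rose and 0 fell (22 and 0 adjusted over the list alone; median 0.32; camera, adjusted p = 1.94e-16, and adjusted p = 0.0484 with an estimated correlation). They included INSIG1 (47.65 to 79.88 TPM), a sterol-sensing regulator, and the sterol carrier STARD4 (24.48 to 38.51 TPM). Of 27 ATF4 and unfolded protein response genes, 22 rose and 1 fell, with equal counts adjusted over the list alone (median 0.28; camera, adjusted p = 2.28e-14, and adjusted p = 0.0484 with an estimated correlation). HSPA5, the endoplasmic reticulum chaperone BiP, rose from 698.2 to 940.8 TPM, DDIT3, which encodes CHOP, from 105.7 to 155.2, the amino acid transporter subunit SLC3A2 from 443.9 to 581.4 and STC2 from 106.8 to 150.7. Of 20 NF-kB and cytokine genes, 10 rose and 0 fell, the same counts as adjusted over the list alone (median 0.23; camera, adjusted p = 7.73e-05, and adjusted p = 0.0484 with an estimated correlation). CXCL1, TNFAIP2 (115.8 to 148.6 TPM), the adhesion molecule ICAM1 (14.96 to 22.04 TPM) and the chemokine CXCL8 (10.83 to 16.05 TPM) led it.

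Of 13 mitochondrially encoded mRNAs in HCT116, 10 fell and 0 rose (11 and 0 adjusted over the list alone; median -0.13; camera, adjusted p = 1.26e-13, and adjusted p = 0.0484 with an estimated correlation). MT-ND6 (log2 fold change -0.38 ± 0.032) and MT-ND5 (-0.32 ± 0.033), subunits of respiratory complex I, fell most clearly. Together the 13 held 28.04% to 28.56% of TPM in vector libraries and 25.68% to 26.11% in CKAP2L libraries. Under quantile normalization, which fixes the highest ranks, 2 of the 13 fell.

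Some EGFR ligand genes and some genes downstream of growth factor receptors also rose in HCT116. The set tests of these lists were lost with an estimated correlation. Of 8 EGFR ligands and receptors, 3 rose and 0 fell (4 and 0 adjusted over the list alone; median 0.18; camera, adjusted p = 0.0013, and adjusted p = 0.156 with an estimated correlation). These were the ligand genes EREG, for epiregulin (56.69 to 90.68 TPM, 0.67 ± 0.039), AREG and HBEGF (21.69 to 27.84 TPM, 0.35 ± 0.048), while the receptor ERBB3 was at 17.86 and 19.75 TPM (adjusted p = 0.0638). Of 20 ERK output genes, 14 rose and 1 fell, also when adjusted over the list alone (median 0.20; camera, adjusted p = 1.65e-06, and adjusted p = 0.169 with an estimated correlation). They included the ERK phosphatase DUSP5 (301.2 to 458.6 TPM), IER3 (1128 to 1389 TPM), PHLDA1 (201.5 to 256.1 TPM) and ETV5 (64.61 to 78.21 TPM). Of 27 growth factor immediate early genes, 16 rose and 0 fell (17 and 0 adjusted over the list alone; median 0.14; camera, adjusted p = 4.57e-07, and adjusted p = 0.13 with an estimated correlation), among them FOS (54.65 to 86.72 TPM), ATF3 (72.77 to 103.7 TPM) and MAFF (41.93 to 54.46 TPM). Of 24 genes of the STAT3 pathway list, 13 rose and 1 fell (14 and 1 adjusted over the list alone; median 0.16; camera, adjusted p = 0.000953, and adjusted p = 0.24 with an estimated correlation). Its first members, FOS, VEGFA (82.41 to 108.5 TPM), ICAM1 and MCL1 (101.8 to 117.4 TPM), are also targets of other pathways. Under median-of-ratios rescaling, 10 of the STAT3 list rose and 2 fell (median 0.10), and 13 of the immediate early genes rose and 1 fell (median 0.08).

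Some cell cycle genes fell in HCT116. Of 40 G2/M and spindle genes, 17 fell and 0 rose (20 and 1 adjusted over the list alone; median -0.11; camera, adjusted p = 1.33e-13, and adjusted p = 0.13 with an estimated correlation). INCENP, a subunit of the chromosomal passenger complex, went from 55.7 to 45.75 TPM, the mitotic kinesin KIF20A from 27.3 to 21.44, the mitotic kinase PLK1 from 95.02 to 81.36 and FAM83D from 24.97 to 19.62. Under median-of-ratios rescaling, 24 of the 40 fell (median -0.17). Of 30 G1/S and replication genes, 8 fell and 1 rose, likewise adjusted over the list alone (median -0.05; camera, adjusted p = 1.88e-05, and adjusted p = 0.219 with an estimated correlation), including GINS2 (30.4 to 26.53 TPM) and the replicative helicase subunit MCM2. Under median-of-ratios rescaling and under quantile normalization, 13 of the 30 fell and 0 rose. Without HCT116 vector replicate 3 the median was -0.03. Of 27 p53 targets, 14 rose and 1 fell (15 and 1 adjusted over the list alone; median 0.16; camera, adjusted p = 8.77e-05, and adjusted p = 0.13 with an estimated correlation). The death receptor gene TNFRSF10B (201.4 to 276.5 TPM), GDF15 (1276 to 1815 TPM), GADD45A (246.8 to 326.9 TPM) and CDKN1A (432.5 to 530.8 TPM) led it. TNFRSF10B, GDF15 and GADD45A are known targets of ATF4 or CHOP as well. Under median-of-ratios rescaling, 12 p53 targets rose and 3 fell (median 0.10). In all, 17 of 21 lists passed camera in HCT116, and 5 held with an estimated correlation, each at an adjusted p of 0.0484. Camera calls at the preset correlation are weak evidence in HCT116: another split of the 6 libraries, which called 0 genes, gave 11 lists.

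**Figure D2:**
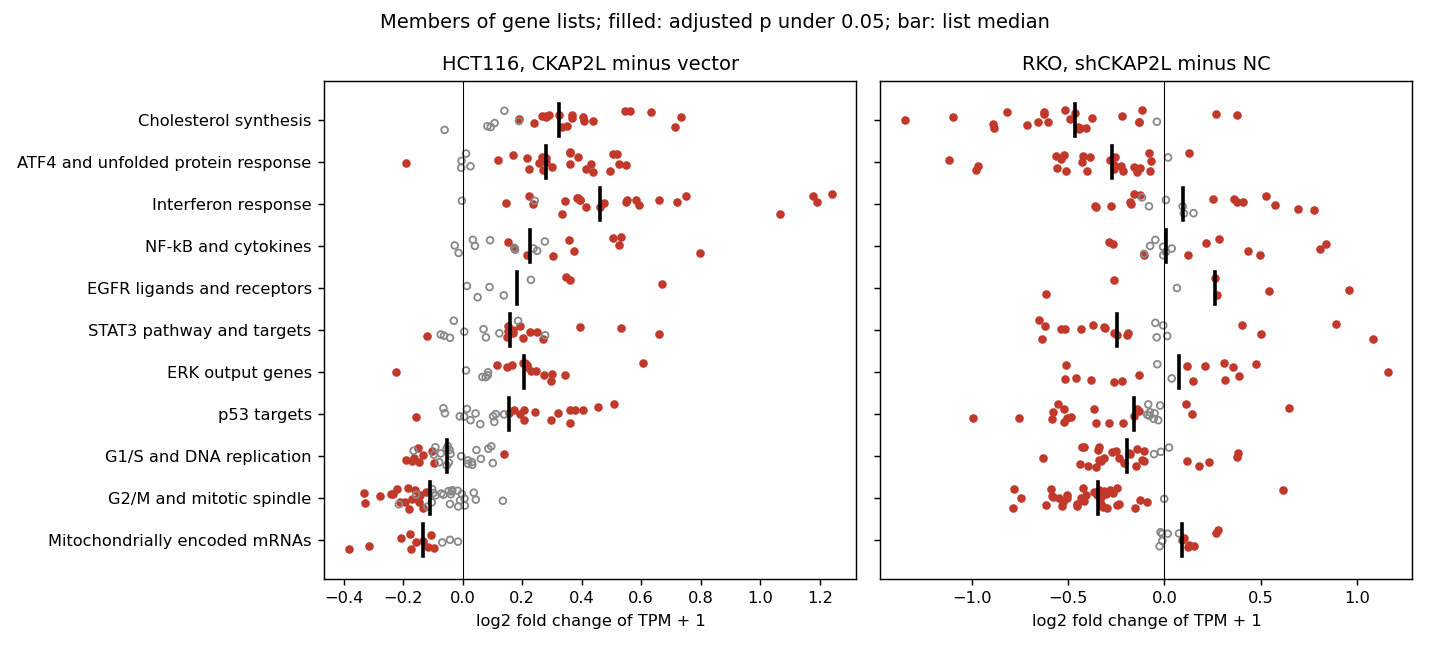
Log2 fold change of TPM + 1 (x axis) of each tested member of 11 gene lists (y axis), in HCT116 on the left and RKO on the right, with different x scales. Filled dots passed the test at an adjusted p under 0.05, open dots did not, and black bars are list medians. Cholesterol synthesis has a median of 0.32 in HCT116 and -0.46 in RKO, and G2/M genes have -0.11 and -0.34.

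In RKO, most tested genes passed the test. Most listed genes of the mitotic spindle, cholesterol synthesis and the ATF4 and unfolded protein response were lower with the knockdown, though the 3 list calls were lost with an estimated correlation (camera, adjusted p = 0.691 for each). The genes with the largest rise were MAP1LC3C, a member of the LC3 autophagy family (48.3 to 190 TPM, log2 fold change 1.95 ± 0.03), SLC41A3, a magnesium transporter family member (9.59 to 33.7 TPM, 1.71 ± 0.05), the phospholipid transfer protein PLTP (2.89 to 11.5 TPM, 1.69 ± 0.06), the co-receptor NRP1 (8.78 to 27.6 TPM, 1.55 ± 0.04) and IRAK1, a kinase of interleukin-1 and Toll-like receptor signalling (126 to 354 TPM, 1.49 ± 0.03). KLF2, a transcription factor, rose by 1.48 ± 0.06, the histone gene H2BC21 by 1.43 ± 0.04, KLHL35 by 1.38 ± 0.06, HMOX1, the inducible heme oxygenase, by 1.37 ± 0.03 and the integrin gene ITGAX by 1.36 ± 0.04. The largest decrease was in CCN2, a matricellular protein and YAP target (39.6 to 11 TPM, -1.75 ± 0.05), before CKAP2L itself. LONRF1 went from 20.6 to 8 TPM (-1.26 ± 0.05), the mTORC1 inhibitor gene DDIT4 from 54.6 to 23.3 (-1.19 ± 0.04) and CCND2, which encodes cyclin D2, from 151 to 66.8 (-1.16 ± 0.03). FSTL3 (-1.13 ± 0.04), the glutathione-degrading enzyme CHAC1 (-1.12 ± 0.04), STARD4 (-1.10 ± 0.03) and the transcription factor KLF4 (-1.09 ± 0.06) fell too. Each had n = 3 per group and an adjusted p of 3.5e-10 or less.

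Altogether 7838 of 11442 genes (68.5%) passed in RKO, 3019 higher and 4819 lower with shCKAP2L (26.4% and 42.1% of tested genes). The median absolute log2 fold change among them was 0.25, and 65 rose and 21 fell by 2-fold or more. The split depended on scaling, with 3987 higher and 3999 lower under median-of-ratios rescaling. Groups did not overlap for 71.4% of genes, where chance gives 10%. Because replicates were this close (median SD 0.0461 on the log2 scale), small changes passed.

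Of 40 G2/M and spindle genes tested in RKO, 38 fell and 1 rose, with equal counts adjusted over the list alone, against 42.1% of all tested genes that fell (median -0.34; camera, adjusted p = 1.08e-09, and adjusted p = 0.691 with an estimated correlation). The mitotic kinesin KIF18B went from 89.13 to 51.44 TPM, PLK1 from 174.4 to 103.8, cyclin A2 (CCNA2) from 108.2 to 71.75 and the anaphase activator CDC20 from 221.5 to 148.4. Of 30 G1/S and replication genes, 22 fell and 5 rose, also adjusted over the list alone (median -0.20; camera, adjusted p = 0.0167, and adjusted p = 0.773 with an estimated correlation), such as GINS1 (66.99 to 42.87 TPM) and the ribonucleotide reductase subunit RRM2 (224.9 to 168.2 TPM). Of 25 cholesterol synthesis genes, 22 fell and 2 rose, both also adjusted over the list alone (median -0.46; camera, adjusted p = 1.18e-06, and adjusted p = 0.691 with an estimated correlation). MSMO1, a sterol enzyme, went from 124.9 to 66.89 TPM and STARD4 from 50.51 to 23.07. Of 26 ATF4 and unfolded protein response genes, 24 fell and 1 rose, likewise adjusted over the list alone (median -0.27; camera, adjusted p = 3.09e-06, and adjusted p = 0.691 with an estimated correlation). CHAC1 (40.08 to 17.96 TPM), XBP1 (145.2 to 73.31 TPM), SESN2 (135.9 to 94.43 TPM) and CEBPB (166.9 to 114.8 TPM) led it. Of 27 p53 targets, 16 fell and 3 rose, as adjusted over the list alone (median -0.16; camera, adjusted p = 0.00676, and adjusted p = 0.773 with an estimated correlation), including BTG2 (46.43 to 22.88 TPM), CCNG1 (217.7 to 153.1 TPM) and DDB2 (55.74 to 36.82 TPM). The camera calls in RKO are weak evidence: another split of the 6 libraries gave 8 lists where the real one gave 7 of 21, and 0 lists held with an estimated correlation.

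Growth factor and cytokine genes went both ways in RKO and none of their lists passed camera. Of 7 EGFR ligands and receptors, 4 rose and 2 fell, also adjusted over the list alone (camera, adjusted p = 0.175). The ligand HBEGF went from 13.11 to 26.42 TPM (0.96 ± 0.042), BTC from 0.737 to 1.53 (0.54 ± 0.081) and ERBB3 from 13.08 to 15.86 (0.26 ± 0.042), against the decreases of AREG and EGFR. EREG was listed at 0 in each of the 6 RKO libraries. Of 21 STAT3 pathway genes, 13 fell and 4 rose, the same adjusted over the list alone (camera, adjusted p = 0.175), with the apoptosis inhibitor BCL2L1 higher (151.9 to 282.6 TPM) and VEGFA (58.63 to 37.81 TPM) and CCND1 (107.8 to 74.99 TPM) lower. Of 18 ERK output genes, 9 rose and 7 fell, also adjusted over the list alone (camera, adjusted p = 0.333), with the potassium channel gene KCNN4 at 45.43 and 102.9 TPM and PHLDA1 at 350.2 and 245.2. Of 21 interferon response genes, 8 rose and 7 fell, also adjusted over the list alone (camera, adjusted p = 0.217), among them HERC6 (11.58 to 20.54 TPM), which rose. Of 17 NF-kB and cytokine genes, 7 rose and 3 fell, likewise adjusted over the list alone (camera, adjusted p = 0.194), such as IL11 (13.53 to 24.97 TPM) and NFKB2 (93.56 to 77.44 TPM).

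Setting the lines side by side asked which genes followed CKAP2L in both directions. Among 11024 genes tested in both lines, 911 changed with opposite signs and 833 with equal signs. Higher with CKAP2L and lower with shCKAP2L were 807 genes, where independent lists would share 794.3 (odds ratio 1.03, Fisher's exact p = 0.52, adjusted 0.52). The reverse held for 104 genes against 122.4 (odds ratio 0.8, Fisher's exact p = 0.0528, adjusted 0.0704). More genes than independent lists would share were higher in both manipulated groups (568 against 486.6, odds ratio 1.3, Fisher's exact p = 3.58e-06, adjusted 7.16e-06) or lower in both (265 against 199.9, odds ratio 1.8, Fisher's exact p = 7.54e-10, adjusted 3.02e-09). Fisher's test takes genes as independent units, which they are not, so these 4 p-values do not by themselves measure evidence of a shared response. Across genes, which are not independent replicates, the fold changes correlated with Pearson's r = 0.039 and Spearman's rho = 0.069. Pearson's r was 0.054 without CKAP2L. With CKAP2L kept, r fell by over 1.5 times with a pseudocount of 5 and at a mean TPM of at least 5. This r moved by at least the SD of its values over the left-out libraries in 10 alternatives, and by less in 10. Among the latter, the requirement of a 2-fold change leaves r unchanged by construction, since r is taken over all genes. The left-out libraries that gave the SD are also among the alternatives counted. Under median-of-ratios rescaling, 687 genes were opposite and 830 equal in sign.

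Among the genes that rose with CKAP2L and fell with the knockdown by most were, after CKAP2L, SCD, the stearoyl-CoA desaturase (0.74 ± 0.03 in HCT116, -0.80 ± 0.02 in RKO), STARD4 (0.63 ± 0.05 and -1.10 ± 0.03), MT1E (0.76 ± 0.05 and -0.57 ± 0.03) and the sterol enzyme MSMO1 (0.56 ± 0.06 and -0.89 ± 0.03). DDIT3 (0.55 ± 0.04 and -0.56 ± 0.03) and ATF3 (0.51 ± 0.04 and -0.97 ± 0.06), stress-induced transcription factors, LURAP1L (0.54 ± 0.05 and -0.51 ± 0.06) and the endothelial lipase gene LIPG (0.60 ± 0.08 and -0.48 ± 0.08) followed. By group, 17 of 25 cholesterol synthesis genes and 20 of 26 ATF4 and unfolded protein response genes were higher with CKAP2L and lower with shCKAP2L, and 0 in either list were the reverse. In contrast, 17 of 40 G2/M and spindle genes were lower in both lines and 0 had opposite calls. Each line gave 1 comparison and members of a list can move together, so such counts are not independent evidence of following CKAP2L. Differences between the cultures that go with the groups could give them too, which was not tested. The reverse pattern, lower with CKAP2L and higher with shCKAP2L, was led by C1orf53 (-0.61 ± 0.16 and 0.69 ± 0.1), MAPK8IP2, a JNK scaffold (-0.35 ± 0.05 and 0.70 ± 0.07), CKMT1B, a mitochondrial creatine kinase (-0.29 ± 0.09 and 0.70 ± 0.07), DNAAF5 (-0.29 ± 0.04 and 0.28 ± 0.04) and the keratin KRT8 (-0.32 ± 0.03 and 0.28 ± 0.04). HSD11B2 (-0.27 ± 0.06 and 0.54 ± 0.05), TMEM158 (-0.27 ± 0.04 and 0.31 ± 0.04), CCDC40 (-0.25 ± 0.08 and 0.28 ± 0.08), FA2H (-0.28 ± 0.05 and 0.25 ± 0.06) and FXYD1 (-0.25 ± 0.07 and 0.50 ± 0.11) followed. The HCT116 calls of C1orf53, CKMT1B, CCDC40 and FXYD1 were lost with no filter. Leaving out 1 HCT116 library, that of CCDC40 was lost without each of the 6, that of C1orf53 without vector replicate 1 or CKAP2L replicate 3, that of CKMT1B without vector replicate 2 or 3 or CKAP2L replicate 1 or 2, and that of FXYD1 without vector replicate 2 or CKAP2L replicate 1 or 3. Those of C1orf53 and CKMT1B were also lost with a constant prior variance, that of CKMT1B with robust empirical Bayes and with the GC and length trend removed, and that of CCDC40 with the replicate block. CKMT1B has a near-identical copy and KRT8, KRT17, MT1E, histone and ribosomal protein genes have close relatives or pseudogenes, so their values depend on how shared reads were assigned. By the size of change, 1 gene, CKAP2L, passed in both lines with opposite signs and 2-fold or more in each.

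**Figure D3:**
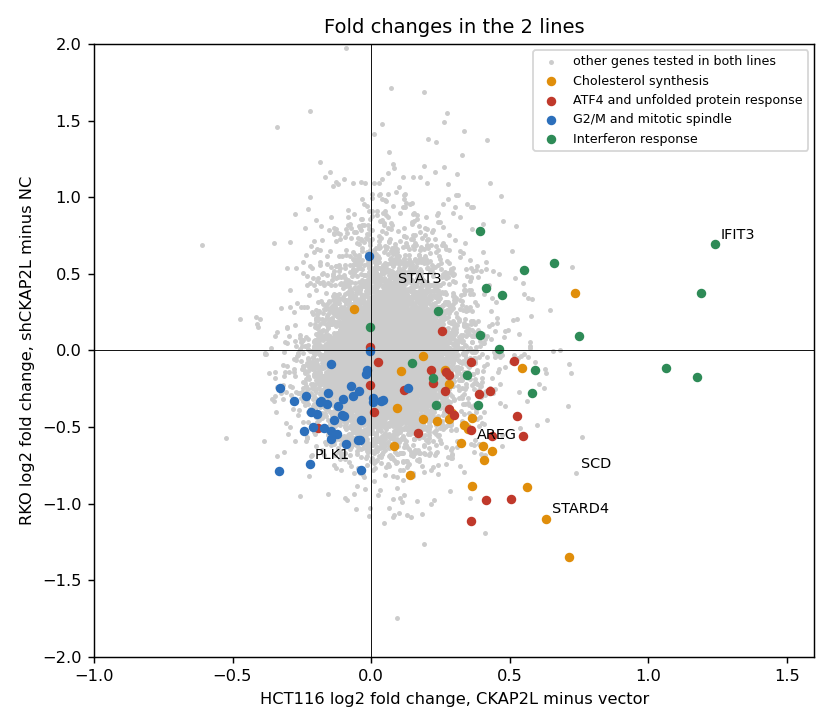
Log2 fold change of TPM + 1 in RKO (y axis, shCKAP2L minus NC) against HCT116 (x axis, CKAP2L minus vector), 1 dot per gene tested in both lines, with 4 gene lists in colour. CKAP2L (3.93 and -1.53) lies outside the axes. Most cholesterol synthesis and ATF4 genes lie at the lower right, and most G2/M genes at the lower left.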

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

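The G1/S test of the G2/M pattern was chosen after the result was seen, and the tests of GC content and length were added after the data were seen. The differences between lines were planned.

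Several changes toward the group with more CKAP2L differed between the lines in the joint limma model, with RKO read as NC minus shCKAP2L. CKAP2L itself changed by 3.93 in HCT116 and 1.53 in RKO, and the contrast is not scaled for this. A difference therefore need not mean an unequal response to the same change of CKAP2L. Nor does the contrast tell an effect of CKAP2L from other differences between the groups. Of 11024 genes, 6010 differed, 3038 with the higher effect in HCT116 and 2972 with the lower. CKAP2L differed by 2.40 on the log2 scale (SE 0.076, adjusted p = 5.18e-14), since its overexpression exceeded its knockdown. STAT3 differed by 0.48 (SE 0.06, adjusted p = 2.05e-06), being higher at the lower CKAP2L level in RKO and not past the test in HCT116. EGFR differed by -0.25 (SE 0.069, adjusted p = 0.00589). AREG moved with CKAP2L in both lines, and the difference of -0.25 did not pass (adjusted p = 0.161), though it passed in 4 of 16 alternatives, with adjusted p from 0.00131 to 0.442. Its size depended on the pseudocount (-0.55 at 0.1) and on single libraries, at -0.43 without RKO shCKAP2L replicate 3 and -0.13 without RKO shCKAP2L replicate 2. The joint model takes 1 spread per gene for both lines, while the SE of AREG was 0.031 in HCT116 and 0.129 in RKO. That the AREG difference did not pass therefore does not show equal effects.

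Among listed genes, the higher effects in HCT116 were those of IFIT3 (difference 1.94), HMOX1 (1.79), H2BC21 (1.76), IFIT2 (1.56) and KLF2 (1.52). IFIT3 and IFIT2 were higher in both manipulated groups, by 1.24 and 1.19 with CKAP2L, while NC minus shCKAP2L in RKO was -0.69 and -0.37. The lower effects were those of CCN2 (-1.66, from 0.09 in HCT116 and 1.75 in RKO), KIF20A (-1.12), KLF4 (-1.01), PLK1 (-0.96) and KRT18 (-0.90). Each of these 10 genes had an adjusted p of 1.74e-08 or less. By list, the median difference was -0.52 for G2/M and spindle genes (camera, adjusted p = 3.07e-15), -0.25 for G1/S genes (adjusted p = 0.000234) and -0.22 for cholesterol synthesis (adjusted p = 0.0126). It was 0.50 for the interferon response (adjusted p = 1.46e-06), 0.33 for NF-kB and cytokines (adjusted p = 0.00384), 0.31 for ERK output genes (adjusted p = 0.00453) and 0.16 for ribosomal proteins (adjusted p = 0.000291). None of the 7 lists held with an estimated correlation, where the adjusted p ran from 0.202 to 0.864.

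Of 100 drawn pairs of splits, 1, the real one, gave as many genes with a difference between lines (6010, highest other 5191). Such a draw asks whether the groups of either line matter at all. It cannot tell whether the effects differ between the lines, since an effect in 1 line gives such genes too. The 88 pairs without the real RKO split gave 0 to 91 genes. The 11 other pairs that kept it, with other HCT116 groups, gave 4256 to 5191, so the RKO groups by themselves gave a large count. These 11 pairs are too few for a share under 0.05 for the HCT116 groups by themselves. For oppositely changed genes, 1 of the 100 pairs of splits, the real one, gave as many (911, highest other 0). This decides nothing, because each other split called 0 genes within its line and a pair with such a split can give no opposite calls.

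Of 40 G2/M and spindle genes, 17 fell in HCT116 and 38 in RKO, although CKAP2L rose in one and fell in the other. Both list calls were lost with an estimated correlation (adjusted p = 0.13 and 0.691). A trend with GC content and transcript length does not account for it, since with that trend removed the list's median minus that of all tested genes was still -0.169 in HCT116 and -0.294 in RKO. Fewer cycling cells in both manipulated cultures remain a candidate explanation. Of 30 G1/S genes, 8 fell in HCT116 and 22 in RKO, against 4.3% and 42.1% of all tested genes. The larger adjusted p of the list was 0.0167 (camera, preset correlation), but the call is lost with an estimated correlation (adjusted p = 0.219 and 0.773). Growth, confluence and cell cycle phase were not analysed here. A direct effect of the CKAP2L level in either direction stays open and untested.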

How the results depend on the processing

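The setting without mitochondrial mRNAs and the removal of the GC and length trend were added after the data were seen. CKAP2L and AREG in both lines, and STAT3 and EGFR in RKO, kept their direction and call under every alternative that tested them (AREG in RKO is not tested at a mean TPM of at least 5). Gene set calls fell from 17 to 5 in HCT116 and from 7 to 0 in RKO with an estimated correlation. At a pseudocount of 0.1, 12 genes were higher and 2 lower by 2-fold or more in HCT116, and 109 and 37 in RKO; at a pseudocount of 5, 2 were higher in HCT116, and 22 and 7 were higher and lower in RKO. The pseudocount sets how far low values can move; at 5, the fold changes of LIPG, C1orf53, CCDC40 and FXYD1 in RKO shrank by over 1.5 times. In HCT116, 341 genes were lower with no filter, which tests more genes, and a constant prior variance gave 1689 changed and 267 lower. The higher and lower genes in HCT116 were 1128 and 1188 under median-of-ratios rescaling, 1102 and 1131 under quantile normalization, and 1158 and 959 without mitochondrial mRNAs. EGFR in HCT116, never past the test, turned to -0.043, -0.048 and -0.033 there. The ribosomal protein list in HCT116, with a median of 0.063 and not past the test, had 0.0044 under median-of-ratios rescaling, where its test turned downward. The correlation of fold changes across genes was 0.0218 with a pseudocount of 5, 0.0248 at a mean TPM of at least 5 and 0.0477 with a pseudocount of 0.1. MT-CO1 in RKO was at 0 under quantile normalization, which ties the top ranks. With a change of 2-fold or more in both lines required, 1 gene was opposite and 0 equal in sign.

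Leaving out 1 library at a time gave 1479 to 3428 changed genes in HCT116, 1183 to 2851 higher and 296 to 577 lower. The count fell by over 1.5 times without HCT116 CKAP2L replicate 1 (1479) and without HCT116 CKAP2L replicate 2 (1717), and genes lower also without replicate 3 (327). Fewer libraries test with less power, but without HCT116 vector replicate 3 the count rose to 3428, which less power does not give. Opposite genes (1249) and genes equal in sign (1053) were also most numerous without that vector library. What sets single libraries apart was not tested. Opposite genes ran from 541 to 1249, with 601 without HCT116 CKAP2L replicate 2, and genes equal in sign from 449 to 1053, with 526 without that library. EGFR in HCT116 ran from -0.0072 to 0.050, STAT3 in HCT116 from 0.052 to 0.11, and the ribosomal protein median from 0.023 (without HCT116 vector replicate 3) to 0.096. Samples share only a number across groups: deviations of same-numbered samples correlated at -0.068, -0.036 and -0.088 in HCT116 and -0.036, 0.049 and -0.043 in RKO, and the replicate block gave 2200 and 7861 changed genes. With the block, 767 genes were opposite and 687 equal in sign, 18 and 7 lists passed, and 5712 genes differed between the lines. Besides CKAP2L, STAT3, AREG and EGFR, 108 genes were followed in HCT116 and 104 in RKO. Of these, 18 in HCT116 and 2 in RKO changed their side of the threshold under some alternative. STAT3 in HCT116 did so too, without HCT116 vector replicate 3. Depth is unknown and sets no stated limit.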

Other observations

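The word search, the TPM without mitochondrial mRNAs and the tests of GC content and length were chosen after the data were seen; the splits of the samples were planned.

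Other gene groups moved less evenly. The HCT116 counts below stand against 16.4% of all tested genes that rose and 4.3% that fell. In HCT116, 12 of 27 apoptosis regulators rose and 1 fell (13 and 1 adjusted over the list alone; camera, adjusted p = 0.00187, and adjusted p = 0.13 with an estimated correlation), among them PMAIP1 (93.95 to 117.5 TPM), which encodes NOXA, and BCL2L2 (24.86 to 31.02 TPM). Under quantile normalization, 8 rose and 1 fell. Of 23 AHR and NRF2 targets, 8 rose and 0 fell (11 and 1 adjusted over the list alone; adjusted p = 0.00268, and adjusted p = 0.184 with an estimated correlation), with HMOX1 at 95.24 and 127.6 TPM, the cystine transporter SLC7A11 at 34.6 and 50.27 and ferritin heavy chain (FTH1) at 2977 and 3533. Under median-of-ratios rescaling, 6 rose and 2 fell. Of 9 histone genes, 4 rose and 0 fell (6 and 0 adjusted over the list alone; adjusted p = 0.0116, and adjusted p = 0.13 with an estimated correlation), including H2AC6 (9.843 to 13.16 TPM). Of 15 WNT targets, 4 fell and 1 rose, also adjusted over the list alone, and 7 fell and 0 rose under median-of-ratios rescaling (adjusted p = 5.3e-05, and adjusted p = 0.232 with an estimated correlation), among them the WNT antagonist DKK1 (509.9 to 409.4 TPM) and BMP4 (200.1 to 170.2 TPM). Hypoxia and glycolysis genes split, 10 of 29 lower and 4 higher (11 and 6 adjusted over the list alone; adjusted p = 0.000891, and adjusted p = 0.219 with an estimated correlation), with LDHA at 636 and 521.5 TPM and DDIT4 at 579.7 and 771.8. Under median-of-ratios rescaling, 12 were lower and 2 higher. Lists that did not pass were epithelial-mesenchymal transition (4 of 14 rose, 5 adjusted over the list alone, adjusted p = 0.078), MYC targets (5 of 30 rose and 4 fell, 6 and 4 adjusted over the list alone, adjusted p = 0.055), colon epithelial identity (4 of 11 rose and 2 fell, the same adjusted over the list alone, adjusted p = 0.247) and ribosomal proteins (9 of 45 rose and 0 fell, 9 and 1 adjusted over the list alone, adjusted p = 0.0719). The MYC target list passed at a mean TPM of at least 5, under median-of-ratios rescaling (9 fell and 3 rose), with the replicate block, without mitochondrial mRNAs, without HCT116 vector replicate 3 and without HCT116 CKAP2L replicate 1. The transition list passed without HCT116 CKAP2L replicate 1. The ribosomal protein list passed with the GC and length trend removed (18 rose), without HCT116 vector replicate 1, without HCT116 vector replicate 2 and without HCT116 CKAP2L replicate 1, while median-of-ratios rescaling left 1 of its genes higher and 2 lower, and quantile normalization 5 and 7. Of the colon epithelial genes, 2 rose and 3 fell under median-of-ratios rescaling, quantile normalization and without mitochondrial mRNAs. For MYC targets and colon identity the median was 0.01 while the test pointed down, below other genes. KRT8 (1758 to 1403 TPM) and KRT18 (2175 to 1870 TPM) fell in HCT116.

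In RKO, 26 of 45 ribosomal protein genes rose and 2 fell, also adjusted over the list alone, with 38 and 0 under median-of-ratios rescaling and 8 lower under quantile normalization (median 0.08; camera, adjusted p = 7.31e-05, and adjusted p = 0.773 with an estimated correlation), such as RPLP0 (3288 to 3887 TPM). Of 13 mitochondrial mRNAs, 7 rose and 0 fell, likewise adjusted over the list alone (adjusted p = 0.0417, and adjusted p = 0.773 with an estimated correlation), but 3 rose and 2 fell under quantile normalization. The list call was lost under median-of-ratios rescaling and without RKO NC replicate 1, RKO NC replicate 2, RKO shCKAP2L replicate 1 or RKO shCKAP2L replicate 3. Their share of TPM was 20.4% to 22.51% in NC and 22.44% to 23.74% in shCKAP2L libraries. The other lists did not pass camera in RKO, and their counts were the same adjusted over the list alone. Of 29 hypoxia and glycolysis genes, 9 rose and 9 fell (adjusted p = 0.474), with ENO1 at 906.1 and 1741 TPM, HK1 at 71.31 and 150.9 and DDIT4 at 54.64 and 23.34. Of 27 apoptosis regulators, 5 rose and 9 fell (adjusted p = 0.811), with the effector BAK1 at 79.54 and 161.9 TPM. Of 17 AHR and NRF2 targets, 4 rose and 9 fell (adjusted p = 0.587), HMOX1 up and NQO1 (61.25 to 42.48 TPM) down. Of 26 immediate early genes, 8 rose and 15 fell (adjusted p = 0.452), of 10 histone genes 1 rose and 6 fell (adjusted p = 0.452), of 13 WNT targets 2 rose and 6 fell (adjusted p = 0.587), and of 30 MYC targets 7 rose and 15 fell (adjusted p = 0.452). Of 12 epithelial-mesenchymal transition genes 5 rose and 4 fell (adjusted p = 0.601), and of 5 colon epithelial genes 3 rose and 1 fell (adjusted p = 0.452), with KRT18 at 149.5 and 92.48 TPM. The median and mean differed in sign for the first (0.10 and -0.10) and for hypoxia (-0.0050 and 0.023), and both tests pointed up.

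Markers of other cell types were mostly under the filter. Of fibroblast markers, COL1A1 alone was tested in HCT116 (41.36 to 46.6 TPM, adjusted p = 0.0132, a call lost under quantile normalization, without mitochondrial mRNAs, without HCT116 vector replicate 2 and without HCT116 CKAP2L replicate 1) and none in RKO. Of immune markers, CD68 was at 31.28 and 27.74 TPM in HCT116 and 1042 and 1065 in RKO, and LAPTM5 at 0.88 and 1.22 in HCT116, none past the test. CD68 passed in HCT116 without HCT116 vector replicate 3, and in RKO under median-of-ratios rescaling and without mitochondrial mRNAs. Of endothelial markers, ESAM was at 27.45 and 30.77 TPM in HCT116 (adjusted p = 0.0731, a test passed with the replicate block and without HCT116 vector replicate 2) and rose from 6.803 to 10.71 in RKO (adjusted p = 6.72e-08). ACTB, chosen after its values were seen, fell from 4050 to 2892 TPM in RKO (log2 fold change -0.48) and from 2282 to 2064 in HCT116 (-0.14).

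More genes were higher than lower in HCT116 with CKAP2L, 79.3% of calls. With the trend on GC content and length removed, 81.9% were higher. The removal kept each library's mean, so a common shift of all genes stayed (median log2 fold change 0.054 before and 0.053 after). The test therefore cannot decide whether such a trend gives the excess. With the 13 mitochondrial mRNAs left out before TPM was rescaled, 54.7% were higher. The smaller mitochondrial share of TPM may therefore give much of the excess, by construction of a share. Whether the mitochondrial share itself follows CKAP2L or the handling of the cultures was not tested.

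Most tested genes changed in RKO with shCKAP2L, 68.5%. Removing the trend with GC content and length left 7934 genes past the test, so that trend does not account for it. Off-target silencing through a hairpin's seed, the bases by which a short RNA pairs with 3' UTRs, was tested by asking which of 16384 words of 7 bases went with lower or higher fold changes, with 3' UTR length and GC content taken out. Direct pairing through the 2 words found, given below, is not the source of most calls: among genes with neither word's 6-base core, 68.7% passed, against 68.9% of all genes searched. The labels name the control only as NC, and that it is a hairpin is an assumption. The hairpins may have other seeds. For every pair of the 4096 possible cores of 6 bases, though, at least 65.1% of genes with neither core in the 3' UTR passed. So 1 seed of the CKAP2L hairpin, with or without 1 seed of a control hairpin, is not the source of most calls by pairing with 3' UTRs, whichever the seeds are. Pairing elsewhere or through further seeds was not tested. Indirect effects of genes silenced in this way are not excluded. The knockdown itself, and differences between the cultures that go with the groups, stay open.

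For part of the changes, seed effects of the CKAP2L hairpin, and of the control if that is a hairpin too, may contribute. The word most tied to lower values was CAGATCA, with z = -7.48 over 11189 genes, against a lowest z of -4.62 for any word in HCT116 and -4.67 in 20 shuffles. The next word, TATTTAT, is AU-rich and does not overlap it in sequence, yet had z = -6.28 in RKO, also past these bounds, so a low z does not by itself mark a seed. CAGATCA lies in the CKAP2L mRNA, in coding exon 4 (bases 543 to 549 of the mRNA; GRCh38 chromosome 2, 112756901 to 112756907), as 21.7% of all words lie somewhere in it. The mean adjusted log2 fold change by site of CAGATCA went from -0.031 ± 0.006 for the last 6 bases to -0.064 ± 0.008 for 7 bases and -0.11 ± 0.019 for 7 bases then A. CAGATCA was picked for its z in these same fold changes, so the step from 6 to 7 bases is not separate support. In HCT116, CAGATCA had z = -0.88.

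The word most tied to higher values in RKO was ACGTGTC, with z = 11.9 (-0.62 in HCT116). It could mark genes held down by the control, if that is a hairpin. The mean adjusted log2 fold change was 0.14 ± 0.011 for its last 6 bases, 0.213 ± 0.021 for 7 bases and 0.214 ± 0.046 for 7 bases then A, so it grew with the site only as far as 7 bases. Only MAP1LC3C of the 10 named higher genes carried the word, fewer than the bound of 2 set beforehand. That bound was ill chosen, since a few top genes cannot exclude an effect on many genes. Of all RKO genes searched, 2.9% carried the word. It was carried by 7 of 61 searched genes at least 2-fold higher and 0 of 19 at least 2-fold lower. Of its carriers, 48.5% were called higher and 21.3% lower, against 24.3% and 44.6% of genes without its last 6 bases. These shares, unlike z, were not adjusted for 3' UTR length and GC content. The word was picked for its z in these same fold changes. Its carriers' direction and the step from 6 to 7 bases are therefore not separate support. The explanation stays undecided because the hairpin sequences were not used here. The 3' UTR of STAT3 holds 1 site of each word, that of EGFR 1 site of CAGATCA, and that of AREG neither.

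In each line there are 10 splits of the 6 libraries into groups of 3, too few for a share under 0.05. Of these, 1 of 10 gave as many genes as the real groups in HCT116 (2625, highest other 0) and 1 of 10 in RKO (7838, highest other 0). As many lists came from 1 of 10 splits in HCT116 (17, highest other 11) and from 3 of 10 in RKO (7, highest other 8).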
